A study of Mus musculus with 16 samples.

How the data were processed

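RNA was measured on 16 Affymetrix mouse arrays, 4 for each combination of treatment (0 or 50 ng/ml AMH) and time (12 or 24 h). Each sample held 6 to 9 follicles and 5 ng of total RNA was amplified and labelled with biotin, per the labels' protocols. The deposited values were linear signal intensities per probe set that the authors made with MAS5, per the submitters' processing notes; its version was not given in the sources used here. The arrays shared a trimmed mean between 149.96 and 149.97 with 2% trimmed at each end, so a scaling to about 150 had been applied before deposit. Detection calls were not analysed here. The correlation of log2 signals between arrays of one group lay between 0.923 and 0.977.

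Signals were turned into log2(signal + 1.46), where the offset was the 10th percentile of all values. Of 45101 probe sets, 64 controls were left out, and 34945 of the others carried a single gene symbol in the annotation table supplied with the data. Probe sets with a mean at or above the 40th percentile (a log2 of 4.18, or a signal of 16.6) were kept, and the probe set with the highest mean stood for each gene, which left 12172 genes. No further scaling was applied. Linear models were fitted with limma 3.58.1 in R 4.3.3, with variances moderated along the mean signal, and p values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A change is the log2 difference between group means, with its standard error (SE) from the moderated fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

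The effect of AMH at 12 h, at 24 h, their mean and their difference came from a fit with the 8 pairs of arrays as a block. The pairing came from the labels, which state that samples are comparable in pairs and that both arms were drawn from one pool. As a check, the deviations of paired arrays from their group means correlated at 0.299, 0.349, 0.56 and 0.214 for replicates 1 to 4 at 12 h, and at -0.437, 0.327, 0.2 and -0.287 at 24 h. The change from 12 h to 24 h in each arm came from a fit of 4 group means without a block, because the labels do not say that both times shared a pool. Within 24 lists of genes, shifts against all other genes were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 24 lists, and again with an estimated correlation. The directional test of fry, a rotation test, asked a different question, whether a list as a whole moved one way from no change, without regard to other genes. The lists and 20 fixed genes were written from known functions. Of the fixed genes 18 were measured, while Cyp19a1 and Lhcgr had no probe set over the filter under these symbols.

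The comparisons, lists, filters, thresholds and the rule for naming genes were set before the data were examined. By that rule the text names, per comparison, the 10 genes with the largest change among those past the threshold whose pairs all moved one way (for times: whose groups did not overlap), filled by smallest p where fewer passed; up to 4 members per list with the smallest p among those past the threshold; and, for AMH, the fixed genes. List members named without having passed, and Dpt, Spon1 and Igfbp5 outside their own comparison, were chosen after their values were seen. On simulated data with 200 changed genes, noise was drawn independently for each gene from its residual spread on these arrays. Between 55% and 77% of genes changed by a log2 of 1 were then recovered per comparison, and between 90% and 97% of those changed by 2. Between 1.84% and 5.23% of the calls were false. These shares hold for that many changed genes and for unlinked genes, and are not the power of the AMH tests.

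Alternatives set in advance were other offsets, filters, scalings (quantile, cyclic loess, median centring), handling of probe sets, array weights, robust moderation, other blocks, fewer arrays in the fit and each replicate left out in turn. Chosen after the data were seen were the oocyte mean or the spike signal as a covariate, crossed pairs at 24 h, arrays rich or extreme in oocyte transcripts left out, and each replicate left out for the lists. For the AMH comparisons the whole pair of such an array was dropped.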

Results

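The series measured transcripts in cultured mouse ovarian follicles with and without anti-Müllerian hormone (AMH), a hormone of the TGF-β family that granulosa cells of small follicles secrete. Follicles between the preantral and small antral stages came from C57BL/6Tac mice, and the follicles of 8 mice were pooled for each experiment. They were then kept in single drops with 0 or 50 ng/ml recombinant AMH, in medium with 80 IU/L follicle-stimulating hormone (FSH) and 10 IU/L luteinizing hormone (LH), and collected after 12 or 24 h. This gave 4 groups of 4 arrays, 16 in all, each from 6 to 9 follicles. Both arms of a pair came from the same pool, so AMH was compared with control within 4 pairs at each time. The number of arrays, 4 per group, limits the precision. The question these comparisons address is which transcripts differ with AMH after 12 h and after 24 h of culture. The median deposited signal per array lay between 27.8 and 40.2, and the arrays shared a trimmed mean of about 150. After filtering, 12172 genes were tested. All changes below are on the scale of log2(signal + 1.46), which understates the change of genes near the floor.

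The arrays held transcripts of several ovarian cell types. The mean log2 signal of 29 oocyte genes was 7.36 ± 0.99 (SD, n = 4) in controls at 12 h, 7.23 ± 0.19 with AMH at 12 h, 7.23 ± 0.67 in controls at 24 h and 7.11 ± 0.63 with AMH at 24 h, and single arrays ranged from 6.07 to 8.45, a 5.21-fold range. Control replicate 4 and AMH replicate 1 held the highest oocyte means of the 24 h arrays. Of the lists fixed as cell type markers, 16 measured stroma and smooth muscle genes ranged over 4.09-fold between arrays, 14 immune genes over 3.68-fold, 15 endothelial genes over 3.75-fold, 13 surface epithelium genes over 3.58-fold and 4 red blood cell genes over 2.10-fold. The second principal component, with 16.2% of the variance, followed the oocyte mean.

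**Figure D1:**
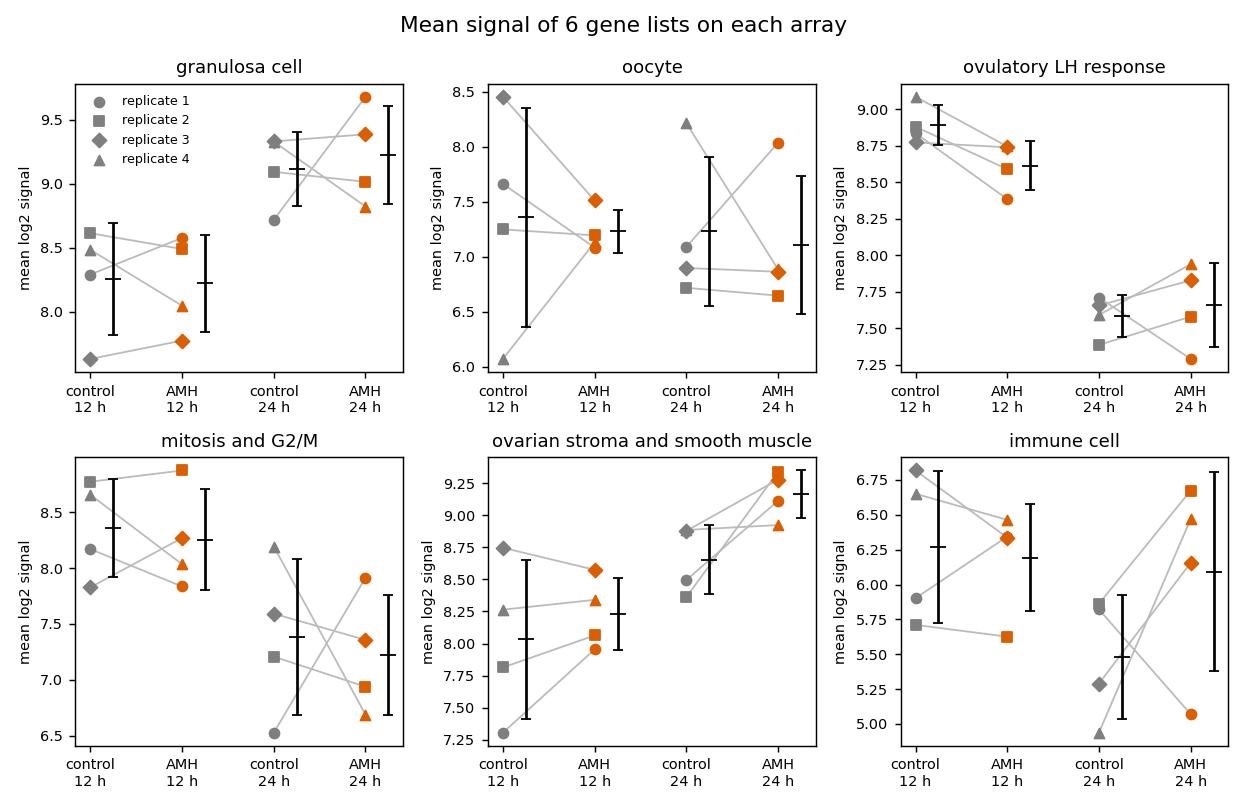
Mean log2 signal of 6 gene lists on each of the 16 arrays (vertical axes), by group (horizontal axes). Points are arrays, grey lines join the control and AMH arrays of one pair, and the bars beside them are group means with the SD (n = 4). The ovulatory LH response list lay lower at 24 h than at 12 h on every array, and the oocyte list ranged from 6.07 to 8.45.

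After 12 h, no gene passed the threshold between AMH-treated and control follicles. The smallest p belonged to Igfbp5, which encodes an insulin-like growth factor binding protein and whose signal was 2.13-fold lower with AMH. Its mean log2 signal was 10.45 ± 0.42 (SD, n = 4) with AMH and 11.55 ± 0.23 without, and it was lower in 4 of 4 pairs, by limma at adjusted p = 0.0813. Vstm4 had a change of 1.79 (SE 0.25, adjusted p = 0.144), Agt, the precursor of angiotensin, of 1.51 (SE 0.27, adjusted p = 0.277) and the potassium channel gene Kcnk1 of 1.33 (SE 0.21, adjusted p = 0.212), each above 0 in 4 of 4 pairs.

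The other genes with the smallest p values among those of one direction in all 4 pairs, a condition of the naming rule that 17.9% of the genes tested met against 12.5% expected by chance, were not past the threshold either. Ephx1, an epoxide hydrolase, had a change of 1.00, the matrix metalloproteinase Mmp11 of 0.83, the sodium pump subunit Atp1b2 of 0.72 and the exocyst gene Exoc4 of 0.55. Alcam, an adhesion molecule, had a change of -0.71 and Sat1, an enzyme of polyamine breakdown, of -0.52. Their adjusted p values lay between 0.212 and 0.277. Of the 18 measured genes fixed for their place in follicle biology, none passed. Cyp19a1 and Lhcgr were not tested, since they had no probe set over the signal filter under these symbols. The AMH receptor Amhr2 had a change of 0.43 (SE 0.16, adjusted p = 0.686), the BMP target Id1 of -0.15 (SE 0.15), Smad6 of 0.49 (SE 0.24), Inhba, an activin and inhibin subunit, of -0.36 (SE 0.26) and Fshr, the FSH receptor, of 0.32 (SE 0.33). Cyp17a1, the androgen-forming enzyme of theca cells, had a change of -0.67 (SE 0.32, adjusted p = 0.778) and was below 0 in 4 of 4 pairs, with -1.76 in pair 1 and a change of -0.30 without replicate 1. Its mean signal with AMH at 12 h lay under the level of the filter, which used the mean over all arrays, so this change rests on low signals. Igf1 had a change of 0.42, Id2 of 0.38, Inhbb of 0.25, Id3 of 0.19, Inha of 0.18 and Star of -0.20. Amh itself had a change of -0.12 (SE 0.52), and Ccnd2, Bmp15, Gdf9, Cyp11a1 and Kitl had changes between -0.10 and 0.03. When each replicate was left out in turn, 7 of the 18 changed sign and 16, all but Amhr2 and Id1, moved by over 1.5 times in either direction at least once: Star was 0.10 and Igf1 0.14 without replicate 1, and Inhbb was 0.81 without replicate 4. Limma called 0 of 12172 genes, with 788 at an unadjusted p under 0.05 against 609 expected by chance.

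In the gene lists at 12 h, 3 of 24 stood below other genes by camera with its preset correlation. The 15 endothelial genes had a median change of -0.39 (adjusted p = 0.00022), with 13 below 0, among them Emcn at -0.48 and Tie1 at -1.08; the adjusted p was 0.419 with an estimated correlation. The 13 surface epithelium genes had a median of -0.30 (adjusted p = 0.00336; adjusted p = 0.691 with an estimated correlation), with the keratins Krt18 at -0.25 and Krt7 at -0.34. The 24 measured genes of the ovulatory LH response, the set that cumulus and granulosa cells switch on before ovulation, had a median of -0.16 (adjusted p = 0.0125; adjusted p = 0.305 with an estimated correlation), with Tnfaip6 at -1.11 and Ptx3 at -1.18. The ovulatory LH response call ended without replicate 4 (adjusted p = 0.0507) and the surface epithelium call without the pair block (adjusted p = 0.0792). No member of these 3 lists passed over all genes, and adjusted over the list alone 1 endothelial gene did. The 16 stroma genes had a median of 0.17 (adjusted p = 0.059), and adjusted over the list alone 4 of them were higher with AMH.

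After 24 h, the genes Dpt and Spon1 were higher in AMH-treated than in control follicles. Dpt encodes dermatopontin, a protein of the extracellular matrix, and rose 3.53-fold, with a mean log2 signal of 8.06 ± 0.26 (SD, n = 4) against 6.25 ± 0.46. Spon1 encodes spondin, a secreted adhesion protein of the matrix, and rose 2.47-fold, to 8.54 ± 0.15 from 7.23 ± 0.45. Both were higher in 4 of 4 pairs, with log2 changes of 1.82 (SE 0.23) and 1.30 (SE 0.16), and both had an adjusted p of 0.048 by limma. The calls were lost in most other settings: Dpt was called in 9 and Spon1 in 8 of 22, no gene was called without replicate 2, without replicate 3, without replicate 4 or without the pair block, and only Dpt without replicate 1. In those fits their changes stayed between 1.70 and 2.05 for Dpt and between 1.16 and 1.42 for Spon1. At 12 h the same genes had changes of -0.11 and 0.15.

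Next in order of p were genes that moved one way in 4 of 4 pairs without passing. That direction was a condition of the naming rule, and 9.39% of the genes tested met it, against 12.5% expected by chance. The transcription factor Snai2 had a change of 0.90 (SE 0.13, adjusted p = 0.134), Tmem204 of 1.12, Hspa1b, a heat-shock protein, of 0.79, the growth factor Fgf2 of 0.79 and Ank, a phosphate transport regulator, of 1.03, while Cela3b had a change of -0.70; these 5 had an adjusted p of 0.207. Slco4a1 had a change of 1.21 (adjusted p = 0.456), with 0.17 in pair 2 against 1.48 to 1.62 in the others, and P2ry14 of 1.14 (adjusted p = 0.469). Among the fixed genes, Cyp17a1 had a change of 1.32 (SE 0.32, adjusted p = 0.652) and Inhba of 0.97 (SE 0.26, adjusted p = 0.813), both above 0 in 4 of 4 pairs. Amh had a change of -0.60 (SE 0.52), Fshr of 0.65 (SE 0.33), Id2 of 0.49 (SE 0.27), Igf1 of 0.37 (SE 0.33), Inhbb of 0.34 (SE 0.55) and Bmp15 of -0.23 (SE 0.36). Amhr2 had a change of 0.01 (SE 0.16), Inha of -0.10 (SE 0.16), Star of -0.44 (SE 0.37), Cyp11a1 of -0.64 (SE 0.39), Kitl of -0.15 (SE 0.16), Gdf9 of -0.14 (SE 0.45) and Ccnd2 of -0.08 (SE 0.27), and all of these had an adjusted p of 1. When each replicate was left out in turn, 9 of the 18 changed sign and 16, all but Cyp17a1 and Inhba, moved by over 1.5 times in either direction at least once. Star and Cyp11a1 stood at -2.17 and -2.50 in pair 1. Without replicate 1 Star was 0.14, Cyp11a1 -0.02, Inhbb -0.48, Igf1 -0.13, Amh -1.26, Gdf9 -0.76 and Ccnd2 -0.45.

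**Figure D2:**
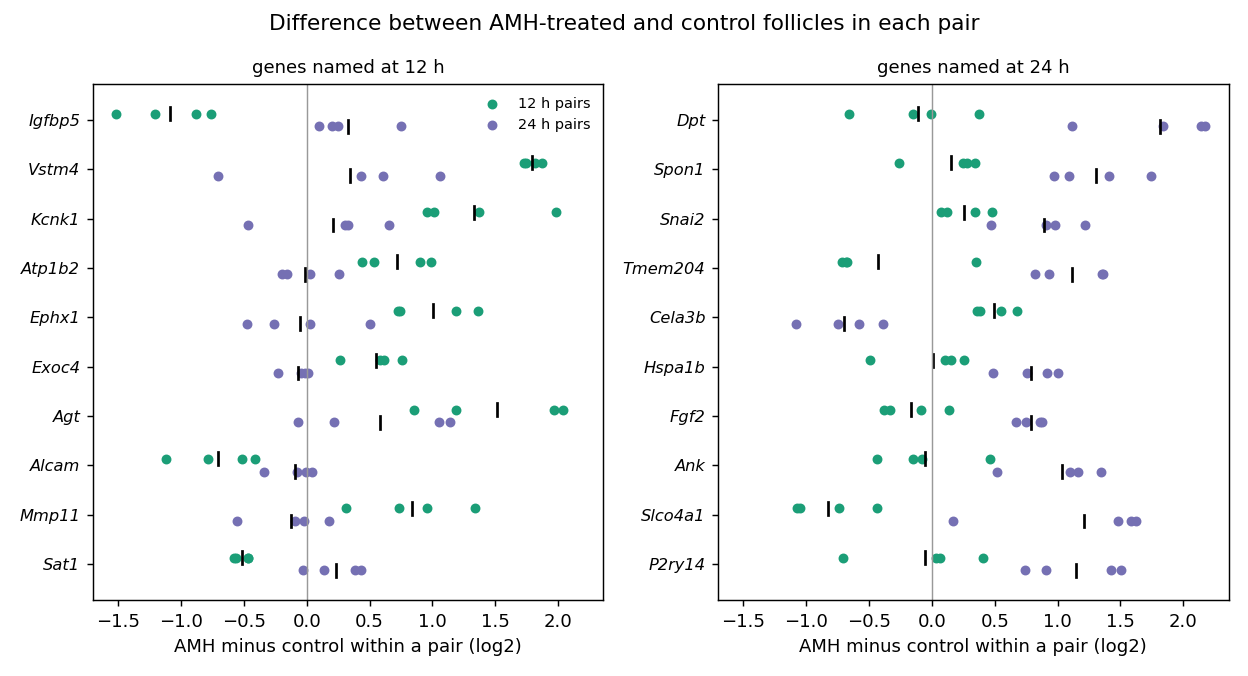
Difference in log2 signal between the AMH and control array of each pair (horizontal axes), for the 10 genes named at 12 h (left) and the 10 named at 24 h (right). Points are pairs, 4 at 12 h (green) and 4 at 24 h (purple) for each gene, and black ticks are their means. Dpt lay between 1.11 and 2.17 in the 24 h pairs, and Igfbp5 between -1.52 and -0.76 in the 12 h pairs.

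Of the lists, 10 of 24 were called at 24 h by camera with its preset correlation, and 0 of them with an estimated one, where the lowest adjusted p was 0.245, or by fry, where it was 0.217. All 16 stroma and smooth muscle genes had values above 0, with a median of 0.41 (adjusted p = 4.33e-10; adjusted p = 0.279 with an estimated correlation); Dpt passed over all genes, 3 were higher adjusted over the list alone, and Dcn, the proteoglycan decorin, stood at 0.67 and Pdgfra at 0.55. All 14 immune genes lay above 0, with a median of 0.68 (adjusted p = 2.06e-06; adjusted p = 0.299 with an estimated correlation), Laptm5 at 1.06 and Cd74 at 0.69. The mean of the immune list ran the other way in pair 1, at -0.75 against 0.81, 0.87 and 1.53 in pairs 2 to 4, and the median change was 1.09 without replicate 1 and 0.46 without replicate 4. Of 12 SMAD1/5/9 targets, the transcriptional read-out of BMP-type receptors, 11 were above 0 and the median was 0.36 (adjusted p = 0.000146; adjusted p = 0.245 with an estimated correlation), with Id4 at 0.97, Smad7 at 0.93, Smad6 at 0.58, Id3 at 0.49, Id1 and Bambi at 0.13 and Bmper at -0.47, and none passed. Id3 was 1.43 in pair 1 and 0.18 without replicate 1, and the median of the list was 0.22 without replicate 1. The medians of the other lists called higher were 0.29 for 15 endothelial genes, 0.18 for 28 extracellular matrix genes, 0.26 for 17 inflammatory cytokine genes, 0.17 for 10 steroid and gonadotropin receptor genes and 0.09 for 29 cAMP signalling genes. With an estimated correlation their adjusted p values were 0.306, 0.326, 0.245, 0.279 and 0.306. The endothelial, extracellular matrix and cAMP calls ended without replicate 2 (medians 0.18, 0.05 and 0.02, adjusted p = 0.278, 0.36 and 0.278). The cytokine and cAMP calls ended without replicate 3 (medians 0.155 and 0.07, adjusted p = 0.124 for both). The receptor call ended without replicate 1, 2 or 3 (medians 0.04, 0.17 and 0.22, adjusted p = 0.235, 0.102 and 0.124). Without the pair block the endothelial, cAMP, cytokine and receptor calls ended. With 24 h pairs 1 and 4 left out, which held the oocyte-rich arrays, the SMAD1/5/9 and receptor calls ended (adjusted p = 0.0634 and 0.0951). That fit dropped both arrays of each of these pairs, so the loss cannot be laid to the oocyte-rich arrays alone. The receptor call also ended with quantile normalization (adjusted p = 0.0702). The stroma median was 0.27 without replicate 2.

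The 20 measured genes of cholesterol biosynthesis all lay below 0 at 24 h, with a median of -0.23 (camera adjusted p = 3.47e-06, and adjusted p = 0.41 with an estimated correlation). The median was -0.13 without replicate 1, and Fdps stood at -0.50 and Hmgcs1 at -0.33. The estimated correlation between members was 0.742, so they are far from independent. By pair the list mean changed by -0.536, -0.345, -0.124 and 0.0492 in pairs 1 to 4, so pair 4 did not share the direction. The 27 mitosis genes had a median of -0.15 (adjusted p = 0.0447; adjusted p = 0.93 with an estimated correlation), and without replicate 4 this list stood above other genes, at a median of 0.29 (adjusted p = 0.0269). It was not called without replicate 2 (adjusted p = 0.278) or without replicate 3 (adjusted p = 0.154) or with the oocyte mean as a covariate (adjusted p = 0.194), and its median was -0.72 without replicate 1. With centring of each array on its median, the median of all genes at 24 h with AMH moved to 0.12, and the list medians to -0.12 for cholesterol biosynthesis, -0.03 for mitosis and 0.21 for cAMP. In total 496 genes had an unadjusted p under 0.05, against 609 expected by chance.

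Averaged over both times, 0 genes passed and the smallest adjusted p was 0.397. Snai2 was above 0 in 8 of 8 pairs with a mean change of 0.57 (SE 0.09), and so were the collagen genes Col6a2 at 0.51 (SE 0.09) and Col1a2 at 0.51 (SE 0.11), Fhdc1 at 0.79 (SE 0.15), Lgals3bp at 0.47 (SE 0.09), the elastic fibre gene Emilin1 at 0.68 (SE 0.14) and Mmp2, a gelatinase, at 0.40 (SE 0.09). Pknox2 at 0.44 (SE 0.10) and Rai2 at 0.46 (SE 0.11) were above 0 in all 8 pairs as well. Zfp982 was below 0 in 8 of 8 pairs, at -0.98 (SE 0.24). Genes of one direction in all 8 pairs made up 0.789% of those tested, against 0.781% expected by chance. Smad6 was above 0 in 7 of 8 pairs, at 0.53 (SE 0.17, adjusted p = 0.946), and the other 17 fixed genes had mean changes between -0.36 (Amh) and 0.49 (Fshr), each at an adjusted p of 0.999. When each replicate was left out in turn, 8 of the 18 changed sign at least once. By limma 585 genes had an unadjusted p under 0.05, against 609 expected.

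For the mean of both times, 7 of 24 lists were called by camera with its preset correlation, and none held with an estimated correlation, where the lowest adjusted p was 0.614. The stroma genes had a median of 0.41 (adjusted p = 2.97e-09; adjusted p = 0.614 with an estimated correlation), the immune genes of 0.37 (adjusted p = 0.00859; adjusted p = 0.63) and the SMAD1/5/9 targets of 0.28 (adjusted p = 0.0379; adjusted p = 0.614). Adjusted over the list alone, 7 of 16 stroma genes were higher. Cholesterol biosynthesis had a median of -0.16 (adjusted p = 7.2e-06), surface epithelium of -0.14 (adjusted p = 0.0193), mitosis of -0.12 (adjusted p = 0.0299) and the oocyte list of -0.12 (adjusted p = 0.036). Only the stroma call held in every other fit tested at the preset correlation. The immune call ended without replicate 4 (median 0.19, adjusted p = 0.314), the SMAD1/5/9 call without replicate 1, 2 or 4 (adjusted p = 0.257, 0.0871 and 0.116), the cholesterol call without replicate 1 (median -0.07, adjusted p = 0.137), the surface epithelium call without replicate 2 or 3 (adjusted p = 0.381 and 0.0543) and the oocyte call without replicate 3 (median -0.01, adjusted p = 0.792). The mitosis call ended without replicate 4, where its median turned to 0.18 (adjusted p = 0.06). With the oocyte mean as a covariate the immune, SMAD1/5/9, mitosis and oocyte calls ended, the oocyte call by construction.

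The difference between the AMH effects at 24 h and at 12 h was tested gene by gene, and no gene passed. Igfbp5 had the smallest p, with a difference of 1.42 (SE 0.19, adjusted p = 0.133), followed by Cela3b at -1.19 (SE 0.17, adjusted p = 0.133), Slco4a1 at 2.04 (SE 0.33), the stress gene Gadd45a at -1.93 (SE 0.32), Dpt at 1.93 (SE 0.32) and Tmem204 at 1.55 (SE 0.26), these 4 at an adjusted p of 0.21. Emcn, an endothelial sialomucin, had a difference of 1.00 (SE 0.17, adjusted p = 0.245), Efs of -1.41 (SE 0.25, adjusted p = 0.261), Olfm1 of 0.99 (SE 0.18, adjusted p = 0.293) and Sat1 of 0.75 (SE 0.14, adjusted p = 0.293). Cyp17a1 had a difference of 1.99 (SE 0.45, adjusted p = 0.323) and Inhba of 1.33 (SE 0.37, adjusted p = 0.533), and the other fixed genes lay between -0.64 (Cyp11a1) and 0.33 (Fshr), while 9 of the 18 changed sign at least once when each replicate was left out in turn. The Cyp17a1 difference rests in part on low signals at 12 h. With 24 h pairs 1 and 4 crossed, an alternative chosen after the data were seen, 23 genes were called, 9 of them higher. By limma 687 genes had an unadjusted p under 0.05, against 609 expected. Camera with its preset correlation called 9 of 24 lists, all higher at 24 h than at 12 h, led by the endothelial genes with a median difference of 0.58 (adjusted p = 2.86e-06; adjusted p = 0.142 with an estimated correlation) and the immune genes with 0.62 (adjusted p = 0.00162; adjusted p = 0.516 with an estimated correlation). Only the endothelial call held in every other fit tested at the preset correlation. Without replicate 3, 7 of the 9 calls ended, among them the immune one (median 0.32, adjusted p = 0.0907), which also ended without replicate 4 (median 0.42, adjusted p = 0.137). With quantile normalization 4 ended, the stroma, surface epithelium, DNA replication and extracellular matrix calls.

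Between 12 h and 24 h of culture, the list of ovulatory LH response genes fell in control follicles, and single granulosa cell genes rose. All arrays came from medium with LH and none from before 12 h. Whether the list had answered to LH could therefore not be tested. Ptx3, a matrix protein of the expanding cumulus, fell 31.7-fold, from a mean log2 signal of 8.52 ± 2.42 (SD, n = 4) to 3.53 ± 0.41, and Ptgs2, the inducible prostaglandin synthase, fell 10.1-fold, from 8.47 ± 0.57 to 5.14 ± 0.78. Fshr rose 4.76-fold, from 3.90 ± 0.92 to 6.15 ± 0.50, and the granulosa transcription factor Foxl2 rose 2.15-fold, from 9.16 ± 0.12 to 10.27 ± 0.19. By limma 2330 of 12172 genes passed, 1212 higher and 1118 lower at 24 h, and 782 of them changed by at least 2-fold.

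The genes with the largest changes among those whose groups did not overlap were Ptx3, the tight junction gene Cldn2 (24.5-fold lower), the cytokine Il11 (23.5-fold lower) and the neuropeptide Nts (a log2 change of -4.17), and, in the other direction, Tmem25 (a log2 change of 4.09), Mybpc3 (15.8-fold), Kif26a (14.8-fold), Mycl (14.4-fold), the lipid droplet gene Plin5 (13.4-fold) and Car3 (12.8-fold). Their adjusted p values lay between 1.9e-05 and 0.00492. Where a mean lay near the floor at one time, as for Ptx3 at 24 h, the fold is understated.

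The ovulatory LH response list fell, with 14 of 24 measured members lower and 1 higher over all genes, and 16 lower adjusted over the list alone. Its median was -0.95 (adjusted p = 2.28e-06), and of the 14 lists called by camera it was the one that held with an estimated correlation (adjusted p = 0.0296), while fry called 8 of 24 lists. Besides Ptgs2, the EGF-like ligand Btc changed by -2.71 (SE 0.28), Errfi1 by -1.42 (SE 0.17) and the hyaluronan receptor Cd44 by -2.05 (SE 0.29). The immediate-early and heat-shock list had 12 of 26 members lower and 0 higher, a median of -0.61 (adjusted p = 2.28e-06; adjusted p = 0.216 with an estimated correlation), with Fosl1 at -2.46 (SE 0.36) and Egr1 at -1.01 (SE 0.21). Of 17 inflammatory cytokine genes 7 were lower, with a median of -0.64 (adjusted p = 0.00598; adjusted p = 0.332 with an estimated correlation), led by Il11 and with Socs3, a feedback inhibitor of cytokine signalling, at -1.17 (SE 0.25). Of 28 extracellular matrix genes 10 were lower and 2 higher, with a median of -0.17 (adjusted p = 0.02, and adjusted p = 0.515 with an estimated correlation). Those lower included the hyaluronan synthase Has2 at -2.75 (SE 0.42) and Tnfaip6, which cross-links hyaluronan, at -3.20 (SE 0.47). The basement membrane collagen Col4a5 rose by 1.81 (SE 0.27). Has2 and Tnfaip6 also stood in the ovulatory LH response list, of whose 24 measured members 12 stood in another list as well.

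Cell cycle lists were lower at 24 h in control follicles. All 27 mitosis genes lay below 0 and 8 passed over all genes, 21 adjusted over the list alone, with a median of -0.99 (adjusted p = 6.73e-07; adjusted p = 0.515 with an estimated correlation), Cks2 at -0.58 (SE 0.11) and Cdc20 at -1.15 (SE 0.35). Of 25 DNA replication genes 4 were lower, 11 adjusted over the list alone, with a median of -0.56 (adjusted p = 0.000201; adjusted p = 0.515 with an estimated correlation), among them Pcna at -0.69 (SE 0.14) and Prim1 at -0.99 (SE 0.22).

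Granulosa and steroidogenic lists were higher at 24 h. These lists are not independent of each other. Of their measured members, 11 of 20 granulosa, 14 of 21 FSH-responsive, 10 of 14 steroidogenesis and 5 of 9 theca genes also stood in another list. Of 20 granulosa genes 11 rose and 0 fell, 13 adjusted over the list alone, with a median of 1.04 (adjusted p = 2.36e-05; adjusted p = 0.358 with an estimated correlation); beside Foxl2 and Amhr2, at 1.01 (SE 0.23), the BMP receptor Bmpr1b rose by 1.20 (SE 0.24). Of 21 FSH-responsive genes 4 rose and 1, Snap25, fell, with a median of 0.79 (adjusted p = 0.00654; adjusted p = 0.379 with an estimated correlation), Inha at 1.01 (SE 0.29) and Nr5a2 at 1.07 (SE 0.30). Of 14 steroidogenesis genes 4 rose and 1 fell, with a median of 0.44 (adjusted p = 0.0328; adjusted p = 0.515 with an estimated correlation), including Hsd17b1, which forms estradiol from estrone, at 1.64 (SE 0.49) and Hsd3b1 at 0.88 (SE 0.20). Of 9 theca genes 2 rose, Aldh1a1 by 1.08 (SE 0.17) and Hsd3b1, with a median of 0.63 (adjusted p = 0.026; adjusted p = 0.358 with an estimated correlation). Of 20 cholesterol biosynthesis genes 2 rose, Tm7sf2 by 1.58 (SE 0.35) and Hsd17b7 by 0.87 (SE 0.21), with a median of 0.28 (adjusted p = 0.0159; adjusted p = 0.74 with an estimated correlation).

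Markers of other cell types shifted as well in control follicles. Of 16 stroma genes 8 rose and 0 fell, with a median of 0.77 (adjusted p = 0.00441; adjusted p = 0.515 with an estimated correlation), such as Dcn at 1.42 (SE 0.24) and Bgn at 0.95 (SE 0.25). Of 14 immune genes 3 fell, the macrophage receptor Csf1r with a change of -2.23 (SE 0.33), Cd74 with -1.74 (SE 0.42) and Cd14 with -1.62 (SE 0.40), and with a list median of -0.64 (adjusted p = 0.0191; adjusted p = 0.515 with an estimated correlation). Of 15 endothelial genes 1, Emcn, fell, with a median of -0.59 (adjusted p = 0.0437; adjusted p = 0.743 with an estimated correlation). The oocyte list, with a median of -0.09 (adjusted p = 0.599) and 0 of 29 members past the threshold, was not called. Of 13 surface epithelium genes 4 fell, Krt8 at -0.84 (SE 0.15) and Krt18 at -1.07 (SE 0.19) among them, and the list as a whole was not called (median -0.32, adjusted p = 0.114).

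The other lists were not called in control follicles. Of 10 steroid and gonadotropin receptor genes 4 rose and 1 fell, with Esr2 at 1.51 (SE 0.39) and Esr1 at 0.62 (SE 0.19) and a list adjusted p of 0.055. The cAMP list had 5 members higher and 2 lower, with Adcy9 at 1.37 (SE 0.23) and Crem, an inducible repressor of cAMP responses, at -1.50 (SE 0.25), at a list adjusted p of 0.65. The list of AMH, BMP and activin pathway genes had 4 higher and 2 lower, with Bmpr2 at 0.70 (SE 0.15) and Bmp6 at -1.44 (SE 0.23), at a list adjusted p of 0.82. The SMAD1/5/9 targets had 1 higher, Id2 at 0.92 (SE 0.24), and 2 lower, Hes1 and Id4, at a list adjusted p of 0.785. Apoptosis genes had 2 higher, Gadd45a at 1.64 (SE 0.33) and Foxo3, and 1 lower, Tnfrsf10b, in a list whose median was -0.04 and mean 0.01 (list adjusted p = 0.785). Glycolysis genes had 2 lower, Slc2a1 and P4ha1 (list adjusted p = 0.124), oxidative phosphorylation genes 2 lower, Cycs and Cyc1 (list adjusted p = 0.277), and red blood cell genes 1 lower, Hbb-b2 at -2.74 (SE 0.52), in a list whose median was 0.28 and mean -0.45 (list adjusted p = 0.9).

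**Figure D3:**
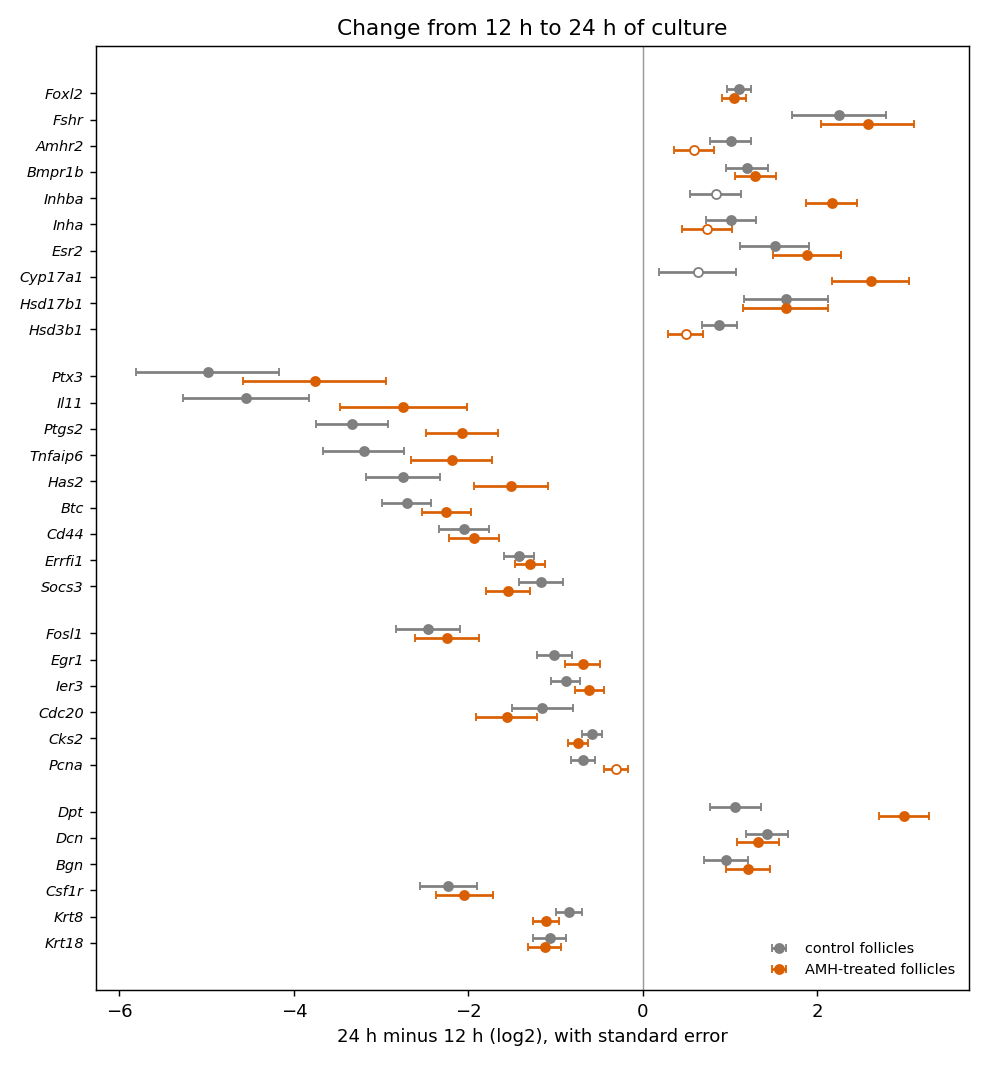
Change from 12 h to 24 h in log2 signal (horizontal axis) of 31 genes, in control follicles (grey) and AMH-treated follicles (orange), each from 4 arrays per time. Points are fitted changes, bars are standard errors, and open points did not pass the threshold. Ptx3 changed by -4.99 in control and by -3.76 in AMH-treated follicles, and Fshr by 2.25 and 2.58.

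With centring of each array on its median in place of the authors' scaling, the median over all genes in control follicles moved from -0.01 to -0.19, and 24.5% of 2496 called genes were higher at 24 h instead of 52.0% of 2330. The directions above are relative to the authors' scaling; no named gene past the threshold and no called list changed sign under any of the 3 other scalings, but 15 of 55 list medians moved by over 1.5 times with median centring, among them cholesterol biosynthesis in controls from 0.28 to 0.10. Without replicate 3 the count was 1185, and without replicate 2 it was 1350. The mean log2 signal of the spiked bacterial transcripts was 10.24 ± 0.37 (SD, n = 4) in controls at 12 h and 9.78 ± 0.18 at 24 h, and with it as a covariate 1213 genes were called. All 2330 genes kept their sign in that fit, with a median absolute change of 0.75 against 0.79 and a median standard error of 0.23 against 0.19. Of the 2330, 46.2% were called again, and 27.3% to 78.9% with spike values shuffled within groups. The slope of the changes with the covariate on those without it was 0.989, and 0.903 to 1.1 with shuffled values. Neither the count nor the size thus tells whether the spike signal bore on the calls.

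In AMH-treated follicles, the ovulatory LH response list also fell from 12 h to 24 h. Fshr rose 5.97-fold and Foxl2 2.06-fold, while Cldn2 fell 16.0-fold, Ptx3 13.6-fold and Ptgs2 4.20-fold. Inhba rose 4.49-fold, from 8.52 ± 0.44 (SD, n = 4) to 10.68 ± 0.50, Cyp17a1 6.11-fold, from 3.69 ± 0.90 to 6.30 ± 0.73, and Dpt 7.95-fold, from 5.07 ± 0.30 to 8.06 ± 0.26. By limma 1008 of 12172 genes passed, 528 higher and 480 lower, 374 of them by at least 2-fold. The other genes with the largest changes were Mybpc3 (12.6-fold higher), Cmtm1 (9.05-fold), Mycl (8.97-fold), the integrin Itga8 (7.92-fold), the anion transporter Slc26a7 (7.84-fold) and Cmtm2a (7.47-fold), and the neuropeptide Nmu (8.06-fold lower).

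By list, 12 of 24 were called, 6 in each direction, and 2 held with an estimated correlation, while fry called 11. The first was the ovulatory LH response, with 9 of 24 members lower, a median of -0.51 (adjusted p = 1.86e-05; adjusted p = 0.0335 with an estimated correlation), Btc at -2.25 (SE 0.28) and Cd44 at -1.93 (SE 0.29). The second was the list of steroid and gonadotropin receptors, with 3 of 10 higher, a median of 0.56 (adjusted p = 0.00114; adjusted p = 0.0335 with an estimated correlation), Esr2 at 1.89 (SE 0.39) and Esr1 at 0.68 (SE 0.19) beside Fshr. Of 20 granulosa genes 9 rose, with a median of 1.03 (adjusted p = 6.39e-08; adjusted p = 0.214 with an estimated correlation), including the monoamine transporter Slc18a2 at 1.99 (SE 0.33). Of 16 stroma genes 5 rose, with a median of 0.92 (adjusted p = 6.09e-07; adjusted p = 0.299 with an estimated correlation). Of 27 mitosis genes 6 fell and all lay below 0, with a median of -0.995 (adjusted p = 2.99e-10; adjusted p = 0.31 with an estimated correlation), such as Cenpe at -1.56 (SE 0.43). Of 26 immediate-early genes 5 fell, with a median of -0.56 (adjusted p = 6.39e-08; adjusted p = 0.0767 with an estimated correlation), such as Fosl1 at -2.25 (SE 0.36) and Klf4 at -1.07 (SE 0.28).

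The remaining called lists in AMH-treated follicles were FSH-responsive genes (median 0.73, 4 of 21 higher), theca genes (0.35, 2 of 9 higher), steroidogenesis (0.49, 2 of 14 higher), DNA replication (-0.27, 1 of 25 lower), inflammatory cytokines (-0.43, 3 of 17 lower, Il11, Ptgs2 and Socs3, and 1 higher, Cxcl12) and glycolysis (-0.29, 0 of 25 past the threshold). With an estimated correlation their adjusted p values were 0.214, 0.299, 0.386, 0.816, 0.312 and 0.816. Igfbp5 rose by 1.44 (SE 0.18), as against a change of 0.02 (SE 0.18) in control follicles. The oocyte list (median -0.11, adjusted p = 0.622) and the immune list (median 0.10, mean -0.10, adjusted p = 0.567) were not called, and neither were the endothelial (median 0.04, adjusted p = 0.759), cholesterol biosynthesis (median 0.12, adjusted p = 0.137) and extracellular matrix lists (median -0.12, adjusted p = 0.298). Csf1r fell (-2.05, SE 0.33). The count was 344 without replicate 4, 364 without replicate 3, 492 without replicate 2 and 638 without replicate 1, and 567 with centring of each array on its median.

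Between control and AMH-treated follicles, the time changes overlapped. Of the 528 genes higher at 24 h with AMH, 403 were also called higher in controls, against 52.6 expected for independent lists, and of the 480 lower, 367 were also called lower, against 44.1 expected; 0 were called in opposite directions. The changes of all 12172 genes correlated with r = 0.784 across genes, which are not independent replicates. Control and AMH arrays of a pair came from one pool, and part of the overlap may come from that. Of the 2330 control calls 1560 were not called with AMH, but the test of the difference between both changes is the one above, which called 0 genes.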

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

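The tests on oocyte share, scaling and crossed numbers below were chosen only after the result was seen. A sample was singled out where its gap to the nearest of the other 3 exceeded the 95% critical value of Dixon's test. Chance flags about 1 in 20 groups, which makes 8.4 of the 168 groups tested, and 7 were found.

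Of the list means, theca cell genes in AMH replicate 1 at 12 h stood at 8.889 against 9.425 to 9.494 in the other arrays, and immune genes in AMH replicate 2 at 12 h at 5.626 against 6.337 to 6.464. Steroidogenesis genes in control replicate 4 at 24 h stood at 8.743 against 9.223 to 9.308. Apoptosis genes in control replicate 3 at 12 h stood at 8.762 against 8.83 to 8.844, and immediate-early genes in control replicate 1 at 24 h at 8.011 against 7.864 to 7.886. Of the differences within pairs, Slco4a1 at 24 h was 0.1688 in pair 2 against 1.48 to 1.62, and Id3 at 24 h was 1.426 in pair 1 against 0.126 to 0.238.

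Lists were singled out where the AMH effect at 24 h differed from that at 12 h by camera on the difference itself with its preset correlation. The median differences were 0.618 for immune, 0.579 for endothelial, 0.321 for surface epithelium, 0.311 for extracellular matrix, 0.285 for SMAD1/5/9 target, 0.28 for ovulatory LH response, 0.269 for inflammatory cytokine, 0.264 for stroma and 0.247 for DNA replication genes. The adjusted p values lay between 2.86e-06 (endothelial) and 0.0395 (stroma, surface epithelium and extracellular matrix). With an estimated correlation they lay between 0.142 and 0.921, and none passed. Without replicate 3, 7 of these 9 calls ended, and with quantile normalization 4 did; the DNA replication median was -0.132 without replicate 1.

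The stroma list, with a median change of 0.411 with AMH at 24 h, was weighed against technical explanations. More stromal tissue carried into the AMH drops cannot be told apart from a change within cells: the median change of the 5 most abundant members, Col1a2, Mgp, Col3a1, Nr2f2 and Bgn, was 0.376, 0.805, 0.117 and -0.0252 in pairs 1 to 4. The scaling between arrays did not account for it, since the median was at least 0.407 under quantile and loess normalization. With the oocyte mean as a covariate the median was 0.428. That mean differed little between the arms (7.109 with AMH, 7.231 in controls), so the covariate could hardly move the median. By pair, AMH minus control, the oocyte mean changed by 0.947, -0.0709, -0.0347 and -1.33 in pairs 1 to 4. The list median changed by 0.575, 0.853, 0.255 and -0.0698. In pair 4, with the largest fall of the oocyte mean, the list was thus not higher. Of 8 assignments of treatment within the 4 pairs, 2 gave a median as large, the real one at 0.411 and another at 0.48. In pair 4 the whole list had a median of -0.0698.

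At 24 h the labelled pairs 1 and 4 did not deviate together, while control replicate 4 and AMH replicate 1 did, with a correlation of 0.538. After removal of each gene's slope on the oocyte mean, taken from the 12 h arrays, the correlation was still 0.5. At 12 h the oocyte mean varied mainly in controls (SD 0.993, against 0.193 with AMH), so that slope rests on few arrays. A shared high oocyte share is therefore not excluded. Crossed numbers cannot be told apart from it or from a chance likeness of these arrays. After the same removal the crossed pairs correlated at 0.264 or more and the labelled ones at -0.421 and -0.164. The crossed pairs were, however, picked from the same correlations. The labels stayed the basis of the pairs.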

How the results depend on the processing

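The covariates, crossed pairs and left-out oocyte-rich or extreme arrays were chosen after the data were seen, and where counts moved the cause was not tested. Of the named genes past the threshold, 40 of 74 in control and 27 of 58 in AMH-treated follicles passed under all 22 settings, 0 of 2 did with AMH at 24 h, and 0 reversed. With AMH at 12 h, 1 gene was called with quantile normalization, 1 with every probe set, 3 with array weights, 2 with pair as a random block and 2 with the oocyte covariate, against 0. With AMH at 24 h the 2 genes became 0 with no offset, no filter, quantile, cyclic loess, every probe set, the mean of probe sets, no replicate block, only the 24 h arrays and the spike covariate; it was 7 with array weights, 4 with crossed pairs 1 and 4, and 0 to 1 without 1 replicate. With 24 h pairs 1 and 4 left out, which held the oocyte-rich arrays, 2 were called, of which 0 were shared. For the mean of both times, 6 were called with array weights, 2 with crossed pairs, 6 without 24 h pairs 1 and 4 and 0 to 1 without 1 replicate. For the difference between times, 1 was called with quantile normalization, 21 with array weights, 2 with the oocyte covariate, 23 with crossed pairs and 0 to 1 without 1 replicate.

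For time in control follicles, 2330 became 3673 with every probe set, 3945 with array weights, 1213 with the spike covariate, 1185 to 1552 without 1 replicate and 1814 without control replicate 3 at 12 h. In AMH-treated follicles, 1008 became 567 with median centring, 1566 with every probe set, 1857 with array weights, 344 to 638 without 1 replicate and 1204 without control replicate 3 at 12 h. A replicate block, with the number as the block, gave 2634 and 1235; the labels do not say that a number was shared across times. Without the pair block the lists called fell from 3 to 2 at 12 h, from 10 to 6 at 24 h, from 7 to 6 for the mean and from 9 to 6 for the difference. Without 1 replicate, 3 to 8, 6 to 16, 5 to 8 and 2 to 12 lists were called for those comparisons, 11 to 16 for time in controls and 9 to 11 with AMH. The list mitosis and G2/M, AMH against control at 24 h, ranged from -0.716 to 0.292 without 1 replicate and reversed without replicate 4. With the directional test of fry, 0 lists were called for each AMH comparison, 8 for time in controls and 11 with AMH. Its test for members moving either way called apoptosis genes with AMH at 12 h (adjusted p = 0.0249) and for the difference (adjusted p = 0.0287). That list holds Gadd45a and Igfbp5, the gene with the smallest p in both comparisons. Adjusted over the list alone, 1 member was higher and 1 lower in each, and the list medians were 0.00381 and 0.0573. Without replicate 3, 7 of the 9 list calls for the difference ended, and without replicate 4, 3 of the 7 for the mean. With quantile normalization 4 of those 9 ended, and with the oocyte covariate 4 of those 7, among them the oocyte list itself by construction. Of the 18 fixed genes, none of which passed for AMH against control, 7 changed sign at 12 h and 9 at 24 h without 1 replicate or another. None of the 55 called lists changed sign under 3 other scalings. Low signals may have limited the precision for genes near the floor, which was not tested.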

Other observations

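The tests on RNA yield, oocyte share between times and separate pools below were chosen only after the result was seen, and the limits for both spike signal tests and the reading of the correlation between the AMH effects were changed after their values were seen. Transcripts with a known place downstream of BMP-type receptors did not pass with AMH on their own. Id1 changed by -0.15 (SE 0.15) at 12 h and 0.13 (SE 0.15) at 24 h, Id2 by 0.38 (SE 0.27) and 0.49 (SE 0.27), and Id3 by 0.19 (SE 0.22) and 0.49 (SE 0.22). Smad6, a feedback inhibitor of this pathway, changed by 0.49 (SE 0.24) and 0.58 (SE 0.24).

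The arrays were regrouped to ask how often other groupings gave as many genes. Of 35 splits of the control arrays into 4 and 4, only the real one reached 2330 genes and the highest other gave 1. Of 35 splits of the AMH arrays, only the real one reached 1008 and the highest other gave 2. Within 4 pairs there are 8 assignments of treatment, too few for a share under 0.05. At 24 h 1 of them reached the real count of 2, with 0 as the highest other. Where the real count was 0, every assignment reaches it by construction (8 of 8 at 12 h, 100 of 100 drawn for the mean of both times and 100 of 100 for the difference between times), so these counts say nothing about chance; the highest other counts were 1, 3 and 3.

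A hypothesis that the AMH effects at 12 h and 24 h share a common part was tested by their correlation across genes. It was -0.0727. A shared part asks for a high value with its sign, and 98 of 128 signed assignments of treatment gave a value as high; the others lay between -0.251 and 0.251, with a median of 0.000979. The value did not stand out from them, so no shared part was seen, and since a small one is not excluded either, the question was left open, where the test had first been read as counting against it.

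The spiked bacterial transcripts were used to ask whether RNA yield separated the times. Their log2 signal at 24 h differed from that at 12 h by -0.468 in control arrays and by -0.125 (SE 0.165) in AMH arrays, with exact permutation p values of 0.0857 and 0.371 where 0.0286 was the smallest possible. By the limit as first written the AMH value counted against yield, and by the later limit, which takes its error into account, yield cannot be told apart from time here. With the spike signal as a covariate, 46.2% of the 2330 control calls were called again, which met the value set for yield as the cause. After this was seen, spike values were shuffled within groups, which gave 27.3% to 78.9% in 20 shuffles, 11 of them as low, and the test was then read as unable to tell. The calls kept their size, with a slope of 0.989 and a median standard error of 0.231 against 0.19, and with shuffled spike values the slope lay between 0.903 and 1.1. The real slope thus lay within the range that spike values without information gave, so it could not decide whether yield set the size of the changes. A part played by yield in the size of the changes or in single calls among the 2330 stays open.

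With the oocyte mean as a covariate 99.7% of the control calls were called again. In controls that mean was 7.36 (SD 0.993) at 12 h and 7.231 (SD 0.673) at 24 h, so no difference in oocyte share between the times was seen. With means so close the covariate could remove few calls, and the share called again does not by itself exclude a part played by the oocytes. Separate pools or culture days for both times cannot be told apart from time: control arrays of one number at 12 h and 24 h had correlations of deviations of 0.134, -0.00642, -0.187 and -0.409 for replicates 1 to 4, and AMH arrays of 0.067, 0.0375, 0.247 and 0.227.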
